A study of Mus musculus with 4 samples.

How the data were processed

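Gene expression was measured in dendritic cells of the colonic lamina propria, the connective tissue layer under the gut epithelium, sorted by flow cytometry from wild-type (WT) mice and from mice labelled as deficient for CD300a (KO), an inhibitory receptor that binds phosphatidylserine on dying cells. Mice were raised under specific pathogen-free (SPF) or germ-free (GF) conditions, which gives 4 groups with 1 array each, and per the labels each condition took cells from 5 mice. Per the labels' protocols, total RNA was amplified as cDNA with a whole-transcriptome kit and labelled with Cy3. The arrays were 1-colour Agilent mouse arrays, and per the file headers they were read with Feature Extraction 10.10.1.1 under protocol GE1_1010_Sep10, with mm9 as the genome build of the design. Both SPF arrays were on slide 1 with scan 1, and both GF arrays on slide 2 with scan 2; per the labels, the SPF mice were female and the GF mice male. Housing therefore cannot be told apart from slide, scan or labelled sex, while each genotype comparison lies within 1 slide. Within the GF pair, however, Xist was well above background on the KO-labelled array only.

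The deposited scanner files hold, per the file headers, a processed signal intensity per spot, which is background-subtracted by the scanner software and not yet scaled between arrays. A deposited table of the whole series also holds intensity values. Set against the scanner files, each of its columns was the processed signal times a constant, 8.30 for WT SPF, 8.24 for KO SPF, 7.08 for WT GF and 7.96 for KO GF, on a linear scale with no centring of genes; the rule that set these factors stays unknown. The medians of its columns were 237.2, 216.3, 235.7 and 331.4 in the same order. It was used as an alternative source of values.

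The main values were log2 of the processed signal minus the 75th percentile of that log2 value on each array, a step computed here from the deposited intensity values. Control spots (3671) and spots flagged as non-uniform or as population outliers were left out, spots of the same probe were averaged, and 84 probes whose spots were all flagged on an array were dropped. The 59305 remaining spots held 55681 probes. The files carry accessions and no gene names, so accessions were matched without version to RefSeq transcripts of GRCm38.p6, from which no coordinate was taken. A name was found for 27223 probes and none for 28458, and 19 probes whose accessions in the files of both slides gave different genes were left unnamed. The named probes covered 20637 genes. Of all named genes 5474 had several probes, and the probe with the highest mean over the 4 arrays stood for the gene. Where a second probe was above background on both arrays, it had the same direction for 80.3% of genes called 2-fold different between genotypes under SPF and for 87.3% under GF housing, and for 75.6% and 85.0% of those different between housings in WT and KO-labelled cells. The second probe was itself at least 2-fold different in that direction for 39.5%, 45.1%, 36.1% and 49.0% of these genes, and the correlations between probes across genes were 0.48, 0.59, 0.42 and 0.60. A probe counted as above background when, by the flag of the scanner software, as many or more of its spots were well above it as were not.

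With 1 array per group no pairwise difference has a replicate check, and no p-value is given for one. A pairwise comparison describes how many genes above background on at least 1 of both arrays were at least 2-fold higher or lower. These counts and the list medians use the measured value also where a gene is below background on 1 array of the pair. For such a gene named in the text a bound is given in place of the difference, the brighter value against the dim probe's value or the dim array's floor, whichever is higher. For a gene shared between pairs, the number expected from independent lists is n1 × n2 / N. Limma 3.58.1 (R 4.3.3, with data.table version 1.17.8 and matrixStats 1.5.0) was fitted to 15030 genes above background on at least 2 arrays, once for genotype with housing as a block and once for housing with genotype as a block, with two-sided moderated tests, Benjamini-Hochberg adjustment and a threshold of 0.05. This leaves 1 residual degree of freedom, which is the genotype by housing interaction. A limma SE or p-value here therefore measures no spread between replicates of a group. Lists of genes fixed before the data were examined, 33 in all with 665 symbols, of which 642 were matched and 9 of these through a synonym, are given by the median difference of their measured members and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. A percentile describes these arrays and is no p-value. Among the listed genes, 23 stand in more than 1 list. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

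Both methods were tested on simulated data for the genotype effect averaged over housing, with the 15030 genes and the spread limma fitted to these arrays. The share of 200 changed genes recovered was 1.16% at a log2 change of 1, 65.9% at 2 and 99.1% at 3, as means over 200 simulations. The adjusted threshold did not hold its nominal rate. The false share of calls, as a mean over simulations, was 39.8% at a log2 change of 1, 12.5% at 2 and 11.7% at 3. A simulation without a call entered this mean as 0. At least 1 gene was called in 111 of 200 simulations at 1, 192 at 2 and 200 at 3, so the first value understates the share among calls. In 91 of 200 simulations with no changed gene at least 1 gene was called, with up to 36 calls. The simulated spread had 10.4 prior degrees of freedom, and limma's estimate of that number had a median of 17.3 and was infinite in 11 of those 200 simulations. With 2500 genes changed by a log2 of 2, the mean false share was 5.63%. For lists of 25 genes under the SPF genotype difference, 4 of 100 unchanged lists fell outside the central 95% of random lists, and 100 of 100 lists shifted by 0.5 lay above it. These lists were drawn at random from the same genes, so the check covers the computation only. It does not cover lists whose members move together.

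The genes named were chosen by a rule fixed before the data were examined: the 10 highest and 10 lowest differences per genotype comparison among genes above background on both arrays, the 10 per direction with the largest smaller difference for shared genotype and housing differences and the 5 per direction for the difference between genotype differences, all among genes above background on the 4 arrays, the 3 highest bounds per direction, the 2 highest and 2 lowest members per list, and always Cd300a, Ifnb1 and the sex-linked genes. Names of clones and predicted genes were left out of the rankings, and not every gene the rule selects is named in the text. Alternatives fixed beforehand were quantile and cyclic loess normalization, background filters on all 4 arrays or none, the mean of all probes of a gene, the deposited table, a 3-fold threshold, a limma prior with an intensity trend and robust fit, and list means. Normexp on mean signals, also fixed beforehand, could not be run because the files used here hold no mean signal column, and it was run on the median signals in its place with an offset of 50.

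On the WT SPF, KO SPF, WT GF and KO GF arrays, 63.4%, 59.5%, 62.4% and 65.0% of probes were well above background, and no spot was saturated (0 on each array). The median standard deviation of log2 signal between repeated spots of a probe lay between 0.09 and 0.10. That is the error within an array only, and the number of arrays limits the precision.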

Results

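Expression profiles of sorted colonic lamina propria dendritic cells were compared between WT and KO-labelled mice under SPF and GF housing, with 1 array per group and cells of 5 mice behind each condition. Of 20637 named genes, 14424 were well above background on the WT SPF array, 13797 on the KO SPF array, 14853 on the WT GF array and 15055 on the KO GF array. Levels are log2 values relative to the array's 75th percentile, and differences are KO minus WT or GF minus SPF on that scale. No pairwise difference has a replicate check.

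Cd300a, the targeted gene, was not lower on the KO-labelled arrays. Its only probe (NM_170758) read 7.88 on the WT SPF array, 7.91 on the KO SPF array, 7.60 on the WT GF array and 8.05 on the KO GF array, levels in the 99.3rd percentile of all genes. Where this probe lies relative to the deleted part of the gene is not given in the sources used here, so the probe does not test the genotype labels, and the arrays are called KO-labelled for that reason. The sex-linked genes did not all follow the sex labels on the KO-labelled arrays. Xist, transcribed from the inactive X chromosome of female cells, read 4.87 and 5.45 on the WT and KO SPF arrays, was not well above background on the WT GF array and read 3.62 on the KO GF array, which is labelled male. The Y-linked genes Ddx3y and Uty were above background on the GF arrays only. Eif2s3y was above background on both GF arrays, at 0.32 and -0.59, and at -2.56 on the KO SPF array, which is labelled female.

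**Figure D1:**
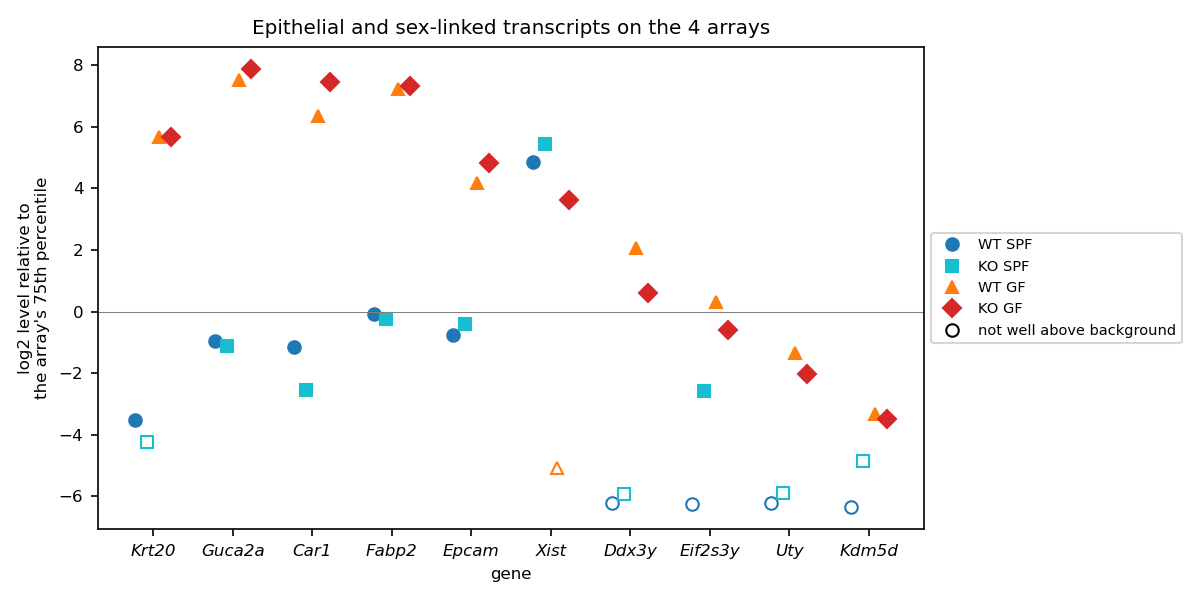
Level of 5 epithelial and 5 sex-linked genes on each of the 4 arrays, as log2 relative to the array's 75th percentile; open symbols are probes not well above background. Guca2a read -0.94 and -1.12 on the SPF arrays against 7.54 and 7.88 on the GF arrays, and Xist read 3.62 on the KO GF array beside the Y-linked genes.

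The first comparison asked how the KO-labelled cells differed from WT cells under SPF housing. Genes of dendritic cell maturation and migration were higher on the KO-labelled array, with 6 of 20 measured members at least 2-fold higher and 0 lower, a median difference of 0.77 and percentile 100 among matched random lists. Among them Ccr7, the receptor that guides dendritic cells to lymph nodes, differed by 2.10, Stat4 by 1.61 and Cd83 by 1.34, while Cacnb3 (-0.81) and Fscn1 (-0.46) were the lowest. Of 26 inflammatory cytokines and chemokines, 6 were 2-fold higher and 5 lower (median 0.19, percentile 99.3). Il6 (2.20) and the neutrophil-attracting Cxcl3 (2.14) were highest, and the monocyte chemokines Ccl8 (-2.80) and Ccl12 (-2.01) lowest. Interferon-stimulated genes were lower, with 0 of 41 members 2-fold higher and 9 lower (median -0.43, percentile 0). Cmpk2 and Ifi47, both at -1.36, were the lowest and Oasl1 (0.92) and Cxcl10 (0.74) the highest. Another probe of Cmpk2 read -0.36. Ifnb1, which encodes interferon beta, was 1.06 higher on the KO-labelled array (0.55 against 1.61), whereas the median of the 7 measured type I interferon genes was -0.46 (percentile 13.8).

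Further groups differed on the same pair. Unfolded protein response genes had a median of 0.60 (percentile 100), with 3 of 18 at least 2-fold higher, led by Chac1 (2.52) and Asns (1.55). Cholesterol synthesis genes had a median of 0.44 (percentile 100), although 0 of 20 were 2-fold higher. Conventional dendritic cell markers (0.38, percentile 99.5) and plasmacytoid dendritic cell markers (0.35, percentile 99.8) had positive medians, with Zbtb46 at 1.45 and Ly6d at 1.46. Of 20 measured genes by which dendritic cells promote regulatory T cells, 6 were 2-fold higher and 2 lower (median 0.17, percentile 97.8), with Vdr and Plat both at 1.55, Aldh1a1 at -1.30 and Tgfb2 at least 1.73-fold lower. The 6 measured aryl hydrocarbon receptor targets had a median of 0.86 (percentile 99.99), of which only Ahr (1.09) was 2-fold higher. MHC class I genes had a median of -0.27 (percentile 0.11), with Tap1 at -0.73, and 0 of 15 were 2-fold different.

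Markers of other cell types moved on this pair as well. B cell and plasma cell markers had a median of 1.36 (percentile 100), with 8 of 15 at least 2-fold higher, among them Pou2af1 (2.33) and Jchain (2.21), the joining chain of secreted antibody. With genes below background on 1 array set to their bound the median was 0.72. Fibroblast and smooth muscle markers (-0.71, percentile 0), endothelial markers (-0.55, percentile 0.09, but -0.17 and percentile 5.22 with normexp on median signals), neutrophil and eosinophil markers (-0.86, percentile 0) and macrophage and monocyte markers (-0.24, percentile 0.08) had negative medians. S100a9 was at -2.02, Plvap at -1.38, Dpt at -1.22 and Ccr2 at -0.70. Of 21 macrophage and monocyte markers, 3 were at least 2-fold higher, with Timd4 at 1.77, and 0 lower. The median of mast cell markers was -0.69 (percentile 0.66, 2 of 6 at least 2-fold lower). That of epithelial markers was 0.23 (percentile 98.8, 5 of 19 higher and 1 lower), but 0.16 (percentile 94.4) under quantile and 0.22 (percentile 96.1) under cyclic loess scaling. Antimicrobial genes were at -0.32 (percentile 2.14, 4 of 12 lower), but at -0.20 (percentile 4) with normexp. The median of T cell markers was 0.14, of innate lymphoid and natural killer cell markers -0.03, of type 1 and type 2 conventional dendritic cell markers -0.08 and 0.10, and of CD300 family and phosphatidylserine receptor genes 0.03. The type 2 and CD300 family medians change sign under quantile and cyclic loess scaling, and the latter also with the deposited table. Cell cycle genes were at 0.19 (percentile 99.1), ribosomal protein genes at 0.17 (percentile 99.5), oxidative phosphorylation genes at -0.14 (percentile 2.47), glycolysis and hypoxia genes at -0.08, retinoid metabolism genes at -0.09, immediate early genes at -0.03, Toll-like receptor pathway genes at -0.06 and MHC class II genes at 0.02, the last with a changed sign under quantile, cyclic loess, normexp and deposited-table scaling. Among all genes above background on both arrays the highest differences were those of Vmn2r26 (4.70), Arhgap33 (3.68), Slc26a6 (3.49), Arap2 (3.39), Gml (3.11), Atp1b1 (2.88), Tox2 (2.61), Areg (2.60), Klk4 (2.58) and Lad1 (2.56). The lowest were those of Fam83a (-5.27), Fam169b (-4.29), Treml1 (-3.77), D2hgdh (-3.12), Dnase1l2 (-3.11), Gata1 (-2.88), Ccl8 (-2.80), Cxcl13 (-2.68), Dapk2 (-2.58) and Bsn (-2.58). Other probes of Slc26a6 (-0.61 and -0.84) and D2hgdh (0.37 and 0.58), above background on both arrays, had the opposite direction. Of genes above background on 1 array only, Ostn was at least 39.4-fold and Clca1 at least 30.0-fold higher on the KO-labelled array. Rimklb was at least 59.4-fold, Olfr695 at least 27.2-fold and Vmn1r10 at least 25.5-fold lower. The Rimklb value rests on its brightest probe, as its other probes were not above background on any array. In all, 835 genes were at least 2-fold higher and 985 lower of 14877 measured. This share was 32.5% in the dimmest quartile of genes and 3.58% in the brightest, and with normexp background correction on the median signals the split turned to 176 higher and 92 lower. It also turned among genes above background on all 4 arrays (443 and 334), among bright genes (188 and 80) and with cyclic loess (917 and 892), and was 724 and 1141 with the deposited table.

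Under GF housing the same comparison gave lower values of many immune genes on the KO-labelled array. The median of all genes was -0.20 and the deposited table's scaling moves each difference of this pair by 0.29, so list medians are also given relative to all genes. That relative value does not allow for brightness, as the median was -0.42 in the brightest quartile of genes. The percentiles do, being matched on mean expression. MHC class II genes had a median of -0.99 (-0.79 relative to all genes, percentile 0), with 7 of 15 at least 2-fold lower, H2-Ob (-1.69) and H2-Oa (-1.65) being the lowest. MHC class I genes were at -0.91 (-0.71 relative, percentile 0.01), with Psmb8 at -1.48. Maturation and migration genes were at -0.85 (-0.64 relative, percentile 0), with 9 of 21 lower and 0 higher. Ccr7 was at -1.91 and Cd80 (0.89, another probe -0.56) was the highest, and Tnfsf4, below background on the KO-labelled array, was at least 1.30-fold lower. Inflammatory cytokines and chemokines were at -0.89 (-0.69 relative, percentile 0), with 12 of 27 lower and 0 higher. Cxcl3 was at least 5.01-fold and Lif at least 2.61-fold lower, since both were below background on the KO-labelled array. Interferon-stimulated genes were at -0.52 (-0.32 relative, percentile 0.34), with 7 of 40 lower and 0 higher, Cxcl10 at -1.55 and Gbp2 at -1.50. Ifnb1 was not well above background on either GF array.

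Conventional dendritic cell markers had a median of -0.93 (-0.73 relative, percentile 0), with 5 of 10 at least 2-fold lower, Ccr7 and Btla (-1.47) being the lowest. Immediate early and dissociation-stress genes were at -0.84 (-0.64 relative, percentile 0) with 10 of 25 lower, led by the heat-shock genes Hsph1 (-2.31) and Hspa1a (-2.08). Cell cycle genes were at -0.81 (-0.61 relative, percentile 0), unfolded protein response genes at -0.81 (-0.61 relative, percentile 0.06) and Toll-like receptor pathway genes at -0.60 (-0.39 relative, percentile 0.19), with Sdf2l1 at -1.33, Nfkbia at -1.38 and the dim Aurkb at least 1.49-fold lower. Ribosomal protein genes were at -0.73 (-0.53 relative, percentile 0), although 0 of 40 were 2-fold different. Oxidative phosphorylation genes had a median of -0.15, which was 0.05 relative to all genes (percentile 97.1) and positive under quantile (0.20), cyclic loess (0.22) and deposited-table (0.13) scaling. Of the other cell types, endothelial markers (-1.03, percentile 0), macrophage and monocyte markers (-0.81, percentile 0.02) and neutrophil and eosinophil markers (-0.85, percentile 0.17) had negative medians, and epithelial markers a positive one (0.72, percentile 100), with 6 of 24 at least 2-fold higher, Muc2 (1.93) and Cdx2 (1.62) being the highest. Type 1 conventional dendritic cell markers were at -0.75 (percentile 0.22, and 5, 4.41 and 4.28 under cyclic loess, normexp and quantile scaling). Other medians were those of type I interferon genes (0.65), T cell markers (0.11), antimicrobial genes (0.07), plasmacytoid (-0.33) and type 2 (-0.55) dendritic cell markers, mast cell markers (-0.54), regulatory T cell-promoting genes (-0.42), CD300 family genes (-0.46), cholesterol synthesis genes (-0.45) and aryl hydrocarbon receptor targets (-0.64). The medians of B cell and plasma cell markers (0.03), fibroblast markers (-0.02), glycolysis genes (-0.22), innate lymphoid and natural killer cell markers (-0.25) and retinoid metabolism genes (-0.23) change sign under at least 1 other scaling.

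The highest GF differences among genes above background on both arrays were those of Lpo (4.95), which encodes lactoperoxidase, the gut hormone gene Pyy (4.19), Zfp623 (3.77), Strip2 (3.72), S100g (3.43), Chga (3.22), Fndc5 (3.19), Tspan9 (3.10), Wdr78 (2.80) and Ube2d-ps (2.76). The lowest were those of Olfr808 (-3.41), Pctp (-3.28), Speer2 (-2.97), Olfr6 (-2.94), Ldhc (-2.63), the small heat-shock gene Hspb1 (-2.61), Cd300ld (-2.60), a relative of Cd300a, Olfr1230 (-2.48), Atoh8 (-2.36) and Hsph1 (-2.31). Another probe of Strip2, above background on both GF arrays, read -1.04. Xist was at least 191-fold, Terf2 at least 39.5-fold by 1 of 3 probes (the others, above background on all 4 arrays, at -0.02 and -0.63) and Spink6 at least 22.2-fold higher, and Olfr99 at least 14.3-fold, Klk1b7-ps at least 12.3-fold and Lipc at least 11.6-fold lower. In all, 1378 genes were at least 2-fold higher and 1221 lower of 15697 measured. This split depended on the processing, with 2291 higher and 571 lower with the deposited table but 512 and 811 among genes above background on all 4 arrays, 283 and 358 with normexp and 158 and 497 among bright genes. The median difference by quartile of signal ran from 0.10 in the dimmest genes to -0.42 in the brightest.

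**Figure D2:**
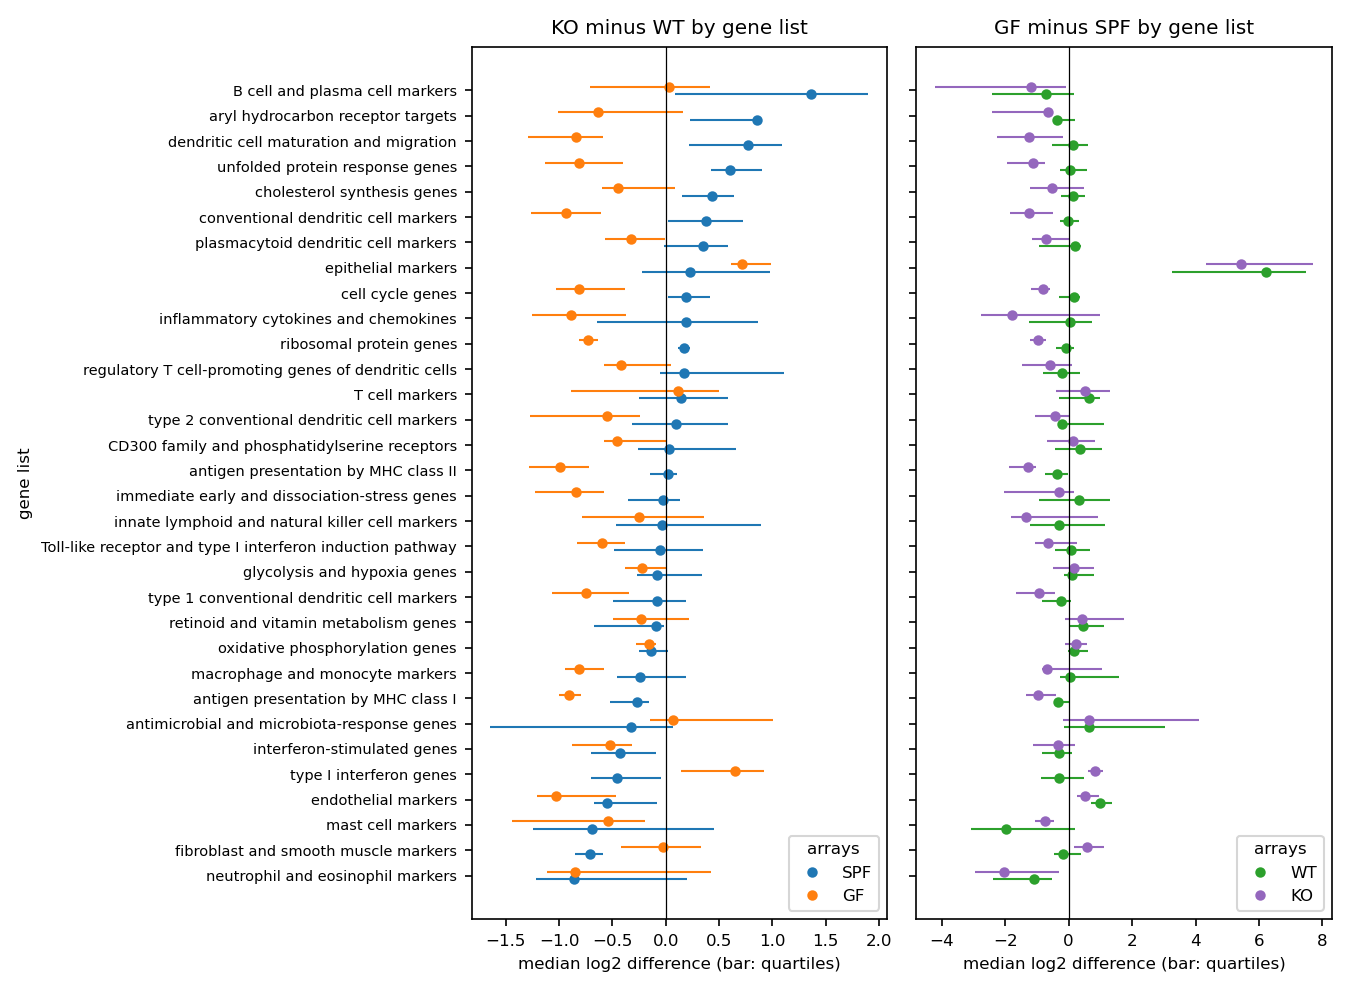
Median log2 difference of each gene list, with bars from the lower to the upper quartile of its members, for KO minus WT on the SPF and GF arrays (left) and GF minus SPF on the WT and KO arrays (right); each comparison is 1 array against 1 array. Maturation and migration genes lie at 0.77 on the SPF and -0.85 on the GF arrays, and epithelial markers at 6.21 and 5.44 in the housing comparisons.

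Few genotype differences were common to both housings. Of 14202 genes measured in both pairs, 115 were at least 2-fold higher on both KO-labelled arrays and 92 lower, where independent lists of these sizes would share 40.1 and 50.3. Another 99 were higher under SPF and lower under GF housing and 103 the reverse, where 47.9 and 42.2 would be shared. The correlation of the 2 differences across genes, which are not independent replicates, was 0.02. The genes with the largest shared difference upward were Lpo (1.69 under SPF and 4.95 under GF housing), Thbs4 (2.05 and 1.58), Sema4g (1.57 and 1.65), Dnah17 (1.57 and 1.55), Fxyd4 (1.54 and 1.70), Sycn (1.52 and 1.80), Foxa2 (1.51 and 1.81), Prrg4 (1.94 and 1.50), Rufy3 (2.15 and 1.38) and Ddc (1.37 and 1.43). Another Ddc probe was below background on the KO SPF array and lower there than on the WT SPF array. Between housings, Thbs4 was 5.13 higher on the GF array in WT and 4.66 in KO-labelled cells. Ddc, Fxyd4, Sycn, Sema4g and Foxa2 also rose there, as epithelial markers did, while Dnah17, Prrg4 and Rufy3 fell. Whether epithelial RNA underlies the genotype differences of the genes that rose was not tested. Downward they were Pctp (-2.38 and -3.28), which encodes a phosphatidylcholine transfer protein, Ccl8 (-2.80 and -1.82), the interferon-induced GTPase genes Gbp6 (-1.68 and -1.53) and Gbp2 (-1.31 and -1.50), Ltb (-1.85 and -1.45), the complement gene C2 (-1.71 and -1.44), Calhm6 (-1.58 and -1.40), Esm1 (-2.19 and -1.35), Retnlb (-1.63 and -1.35) and the B cell chemokine Cxcl13 (-2.68 and -1.31). With the deposited table the shared split was 169 higher and 62 lower, and with normexp on the median signals 3 and 10.

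**Figure D3:**
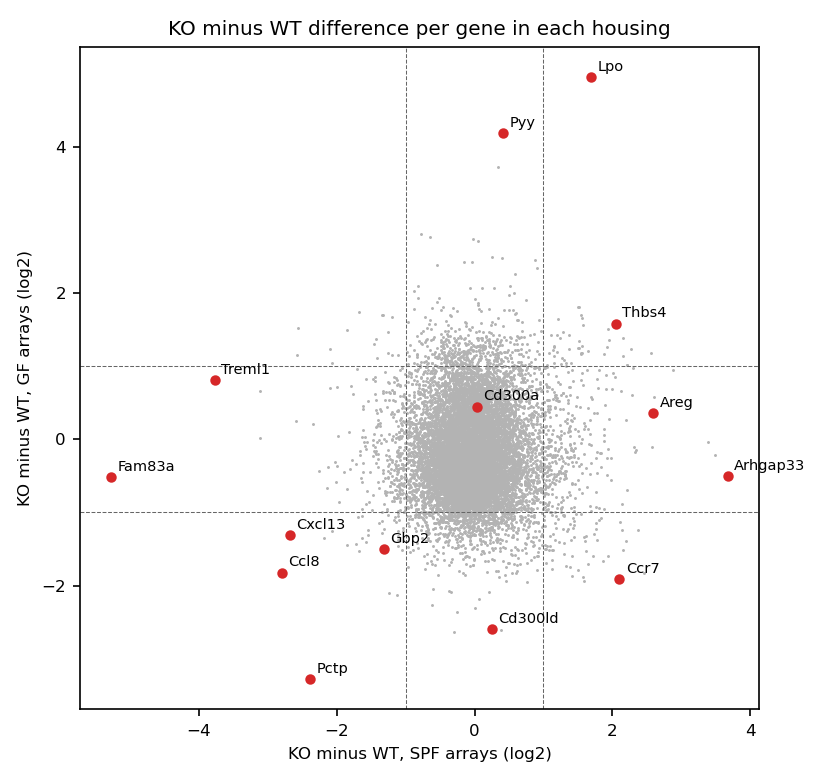
KO minus WT difference of each gene above background on all 4 arrays, on the SPF arrays (x axis, log2) against the GF arrays (y axis, log2); each point is 1 gene and dashed lines mark 2-fold. The correlation across genes was 0.02; Pctp lies at -2.38 and -3.28, Ccr7 at 2.10 and -1.91.

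For the genotype effect averaged over housing, limma with housing as a block called 11 genes higher and 10 lower of 15030 tested (958 at an unadjusted p under 0.05). This number of calls does not exceed what the fit can give with no genotype effect, since 15 of 200 simulations with no changed gene gave at least 21 calls. With the prior degrees of freedom set to 5 or to 20, in place of the estimated 10.4, the counts were 0 and 0 or 39 and 30. Quantile, cyclic loess and deposited-table values each gave 0 calls, whereas genes above background on all 4 arrays gave 26 and 12 and an intensity trend with robust prior 53 and 24. These last exceed the largest number of calls in the simulations with no changed gene (36). They do not exceed the 81 false calls reached where 200 genes were changed by a log2 of 3. All simulations were run for the main setting only. The genes are therefore given as values without a call. Of the 21, only Pctp was above background on all 4 arrays (-2.83, SE 0.41, limma adjusted p 0.0363). Chga, which encodes chromogranin A, was below background on the WT SPF array, so its difference was at least 6.03-fold under SPF and 3.22 under GF housing.

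The difference between the genotype differences, SPF minus GF, was at least 4-fold upward for 337 genes and downward for 385, with no residual degree of freedom for a test. Fut1 (4.29), Arhgap33 (4.19), Ccr7 (4.01), Slc26a6 (3.71) and Apold1 (3.67) were the highest among genes above background on the 4 arrays. The lowest were Fam83a (-4.75), Treml1 (-4.58), Pyy (-3.78), D2hgdh (-3.77) and Bsn (-3.72). The values of Slc26a6 and D2hgdh rest on 1 probe each, as other probes above background on the 4 arrays gave 0.28 and -1.18 for Slc26a6 and 0.63 for D2hgdh. Ccr7 read 1.91 on the WT SPF, 4.01 on the KO SPF, 1.37 on the WT GF and -0.54 on the KO GF array. With the deposited table the split was 188 and 641. It turned to 365 and 317 with quantile normalization, 364 and 289 with cyclic loess, 194 and 89 among genes above background on all 4 arrays, 113 and 15 among bright genes and 70 and 15 with normexp.

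The housing comparison set the GF arrays against the SPF arrays, which also differ in slide, scan and labelled sex. Its limma SEs and p-values rest on how alike both genotypes were, moderated over all genes, and not on replicates of a group. Epithelial genes rose together. Of 24 epithelial markers 23 passed limma's threshold upward and 0 downward over all genes tested, and 24 adjusted over the list alone. The list's median was 6.21 in WT and 5.44 in KO-labelled cells (5.39 relative to all genes, percentile 100 in both). Guca2a, the guanylin gene of the gut epithelium, was 8.74 higher on average (SE 0.40, limma adjusted p 3.03e-07), Lypd8 8.36, the carbonic anhydrase gene Car1 8.74, the fatty acid-binding gene Fabp2 7.42, Cyp2c55 7.77, Dmbt1 6.77, Ces2b 6.96, Fcgbp 6.78, Btnl5-ps 6.68 and Cdhr5 7.09. Another Btnl5-ps probe above background on the 4 arrays read -0.19 in WT and 1.49 in KO-labelled cells. Antimicrobial and microbiota-response genes also held 8 of 17 that rose and 3 that fell (8 and 3 adjusted over the list alone), with Slpi at -3.89 in WT and -4.54 in KO-labelled cells. Saa2, below background on both SPF arrays, was at least 405-fold higher on the GF array in WT and at least 606-fold in KO-labelled cells, and Reg3b, also below background there, at least 11.9-fold and 32.1-fold. Whether the antimicrobial transcripts that rose came from dendritic cells or from the same source as the epithelial transcripts was not tested. In the macrophage and monocyte list 6 of 21 rose and 1 fell (7 and 1 over the list alone), the tissue-resident macrophage genes Fcna (5.68 and 4.55) and Folr2 (4.27 and 3.86) being the highest and Ccr2 (-2.04 and -2.52), the receptor of blood monocytes, the lowest. Lyve1, of lymphatic endothelium and some resident macrophages, was at 5.74 and 5.86, and Aldh1a1, a retinoic acid-producing enzyme gene, at 4.71 and 6.92.

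Other lists held genes that fell on the GF arrays. Of 13 B cell and plasma cell markers tested, 6 fell and 1 rose (6 and 1 adjusted over the list alone). Jchain was at -6.42 on average (SE 0.58, limma adjusted p 1.49e-05) and Pou2af1 was at -4.10. Of 27 inflammatory cytokines and chemokines 8 fell and 1 rose (11 and 5 over the list alone), with a median of 0.05 in WT (0.00 with normexp, of the opposite sign) and -1.78 in KO-labelled cells. Of 25 immediate early and dissociation-stress genes 9 fell and 3 rose (10 and 5 over the list alone), Hspa1a being at -1.89 and -3.63 and Egr1 at 2.57 and 2.33. The median of this list was 0.33 in WT (percentile 99.2) and -0.31 in KO-labelled cells (percentile 54.6), the latter positive under quantile, cyclic loess and deposited-table scaling. Of 11 neutrophil and eosinophil markers 6 fell (6 over the list alone), with Prg2 at least 8.53-fold lower in WT and at -3.53 in KO-labelled cells. Among the largest shared falls were those of Jchain, Slpi, Gcnt2 (-3.84 in WT and -4.23 in KO-labelled cells), Pgf (-3.33 and -5.65), Lsmem1 (-3.32 and -3.20), Syne1 (-3.59 and -2.95), Pou2af1 (-2.85 and -5.35), Csf1 (-3.53 and -2.84) and Peg10 (-2.92 and -2.83). Another probe of Syne1 was higher (0.47 and 1.39) and another of Gcnt2 read 0.13 in KO-labelled cells. Ifnb1 was above background on the SPF arrays only, at least 22.6-fold higher there in WT and at least 46.9-fold in KO-labelled cells. Interferon-stimulated genes had medians of -0.30 in WT (percentile 0.26) and -0.34 in KO-labelled cells (percentile 4.58), the latter 0.00 with the deposited table.

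In WT cells 2741 genes were at least 2-fold higher on the GF array and 1478 lower of 15657 measured, and in KO-labelled cells 3368 and 2397 of 15572. Of these, 1664 and 707 were shared, with a correlation across genes of 0.72. Averaged over genotype, limma called 1712 genes higher and 782 lower (4507 at an unadjusted p under 0.05). The share of false calls was simulated for the genotype effect only, not for housing. With the deposited table, whose scaling moves the KO-labelled housing difference by 0.34, the KO-labelled split was 4613 and 1501 and the limma split 1278 and 289. The KO-labelled split turned to 1774 and 1973 among genes above background on all 4 arrays, 1208 and 1258 with normexp and 641 and 1304 among bright genes, where the limma split was 553 and 696. Dendritic cell lists differed by housing mainly on the KO-labelled pair, with maturation and migration genes at a median of 0.15 in WT and -1.26 in KO-labelled cells and MHC class II genes at -0.37 and -1.27; this difference was not tested.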

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

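The tests below were chosen after the results were seen, except the second epithelial list and the cyclic loess test of the maturation genes, which were set out before their values were seen. The medians of 6 gene lists lay above the central 95% of random lists under SPF and below it under GF housing. Further lists had medians of opposite sign without meeting this limit, such as aryl hydrocarbon receptor targets (0.86 and -0.64). This difference between housings was not tested, since 1 array per group leaves nothing to test it with. The SPF minus GF difference of the list medians was 1.62 for dendritic cell maturation and migration, 1.41 for unfolded protein response genes, 1.31 for conventional dendritic cell markers, 1.08 for inflammatory cytokines and chemokines, 1.003 for cell cycle genes and 0.91 for ribosomal protein genes.

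Maturation genes had a median of 0.77 under SPF and -0.85 under GF housing. An intensity-dependent scaling of the KO GF array is argued against as the whole cause, because after cyclic loess normalization the GF median was -0.59 and stayed below the central range of random lists. A lower share of dendritic cell RNA on that array stays open. The distance of 0.14 between the maturation and MHC class II medians there would go with it. A rise of all other cell types alike is argued against, as the epithelial median exceeded the endothelial one by 1.74 (larger interquartile range 0.75). That comparison cannot decide on a larger epithelial share alone (epithelial median 0.72). Such a share would lower the endothelial (-1.03), macrophage (-0.81) and neutrophil (-0.85) medians as well. Fibroblast (-0.02), T cell (0.11) and B cell and plasma cell (0.03) markers did not follow it, as their medians lay above that of all genes (-0.20). A higher dendritic cell share on the KO SPF array stays open. The maturation and MHC class II medians lay 0.75 apart there, within the larger of the interquartile ranges of both lists (0.87). That limit replaced the range of the MHC class II list alone, which 0.75 exceeds, after the value was seen. Conventional (0.38) and plasmacytoid (0.35) dendritic cell markers were higher on that array and fibroblast (-0.71), endothelial (-0.55), neutrophil (-0.86) and macrophage (-0.24) markers lower, which such a share would give. B cell and plasma cell markers (1.36), epithelial markers (0.23) and MHC class II genes (0.02) did not follow it. Neither did type 1 (-0.08, percentile 45.3) and type 2 (0.10, percentile 77.2) conventional dendritic cell markers. Of 21 macrophage and monocyte markers, 3 were at least 2-fold higher and 0 lower. Other differences between single preparations of cells and a dependence of the genotype effect on housing stay open, both untested.

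Epithelial transcripts were higher on both GF arrays. Scaling between the slides is argued against, since the epithelial median exceeded the ribosomal protein median by 6.30 in WT cells (interquartile range of the epithelial list 4.21). Carry-over of epithelial cells or their RNA into the sorted GF cells is a candidate explanation. Of a second list of 27 epithelial transcription factor, junction and polarity genes, 24 (88.9%) were at least 2-fold higher on the GF arrays in both genotypes. Guca2a (7.54 and 7.88) and Fabp2 (7.22 and 7.31) were among the brighter genes there. A flow cytometry sort is meant to remove such cells, and how far it did so was not tested. Epcam also stands in the list of type 2 conventional dendritic cells, but it is 1 of 24 epithelial markers. Housing, sex and slide cannot be told apart as the origin of this difference, because 0 GF arrays lay on the SPF slide.

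Xist stood beside Y-linked transcripts on the KO GF array, which is labelled male. Cross-hybridisation of 1 Xist probe is argued against, as 2 Xist probes were above background there and at least 4-fold higher than on the WT GF array. A swap of the KO arrays is argued against, as only 1 Y-linked gene was above background on the KO SPF array, which also carried Xist. RNA of both sexes in the KO GF sample is a candidate explanation, since Xist and the Y-linked genes were above background together. The median of the Y-linked genes was at -0.79 against the WT GF array, which such a mix would give. It cannot decide, because ribosomal protein (-0.73) and MHC class I genes (-0.91) had similar medians on this pair, where that of all genes was -0.20. Whether mice of both sexes were pooled is not given in the sources used here. With such a mix, the GF genotype differences would also compare samples of unlike sex make-up, which these arrays cannot separate from genotype. The shared genotype differences and the differences between genotype differences use the same GF pair.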

How the results depend on the processing

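The alternatives normexp on median signals, bright genes only, genes not higher in GF and fixed prior degrees of freedom were chosen after the data were seen; the others were fixed before the data were examined. No paired analysis was possible because the labels carry no replicate numbers that pair samples and each group has 1 array; the housing term of the genotype fit compares genotypes within a slide. Of the values under alternatives, 889 list medians, 75 counts and 392 gene values stayed within a tolerance, while 396 list medians, 93 counts and 332 gene values moved beyond it. The tolerance was a factor of 1.5 for a count and 0.14 for a log2 value, the spread of a difference between repeated spots within an array. Of 1289 list medians under alternatives 85 changed sign, of which 4 lay outside the central 95% of random lists in the main analysis. The set of genes not higher in GF gave 17 of the 85 and 2 of the 4; this set leaves out genes by their housing difference, so it lowers housing medians by construction and is no test of them. Counts are given as higher and lower, and unless a reason is named the cause was not tested. A 3-fold threshold by construction gave fewer genes: 365 and 450 for genotype under SPF, 470 and 306 under GF, 22 and 16 shared, and 1570 and 679 for housing in WT and 2074 and 1076 in KO-labelled cells. Genes above background on all 4 arrays, a smaller set, gave 443 and 334 under SPF, 512 and 811 under GF, 45 and 35 shared, 1509 and 874 for housing in WT, 1774 and 1973 in KO-labelled cells, 194 and 89 for the difference between genotype differences, and 26 and 12 by limma for genotype. Bright genes only, also a smaller set, gave 188 and 80 under SPF, 158 and 497 under GF, 15 and 15 shared, 685 and 424 for housing in WT, 641 and 1304 in KO-labelled cells, 113 and 15 for the difference between genotype differences, and by limma 10 and 2 for genotype and 553 and 696 for housing. Without a filter on dim probes the counts were 1427 and 1505 under SPF, 269 and 190 shared, 757 and 891 for the difference between genotype differences, 0 and 0 by limma for genotype and 386 lower for housing, and the mast cell median for housing in WT changed sign to 0.16. Normexp on median signals gave 176 and 92 under SPF, 283 and 358 under GF, 3 and 10 shared, 993 and 452 for housing in WT, 1208 and 1258 in KO-labelled cells, 70 and 15 for the difference between genotype differences, and by limma 0 and 0 for genotype and 817 and 446 for housing. The deposited table gave 2291 and 571 under GF, 188 and 641 for the difference between genotype differences, 1501 lower for housing in KO-labelled cells, and by limma 0 and 0 for genotype and 289 lower for housing. Limma for genotype gave 0 and 0 with quantile normalization, with cyclic loess (420 lower for housing) and with the mean of all probes, where the innate lymphoid and natural killer cell median for housing in KO-labelled cells changed sign to 0.022, and 53 and 24 with an intensity trend and robust prior (1302 lower for housing). With the prior degrees of freedom set to 5 limma gave 0 and 0 for genotype and 1087 and 300 for housing, with 8 it gave 2 and 1 for genotype, with 15 it gave 19 higher, with 20 it gave 39 and 30, and with an infinite prior 218 and 132 and 1404 lower for housing. Among genes not higher in GF, the counts were 646 and 993 for genotype under GF and 43 and 77 shared. Leaving out genes with high values on the KO GF array lowers that genotype difference too, so the turn of both splits is no test of them. By the same choice of genes the antimicrobial median for housing in WT changed sign to -0.12 and the immediate early median to -0.52. Dim genes limit the pairwise counts, as 32.5% of the dimmest quartile and 3.58% of the brightest differed 2-fold under SPF housing. Normexp on mean signals was not run, because the files hold none.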

Other observations

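Both gene sets below were chosen after their first members were seen, and their values are descriptions of the same arrays. Of 18 interferon-induced GTPase genes taken by name after Gbp2 and Gbp6 were seen among the shared differences, 12 remained without these 2 and the members of the interferon-stimulated list, whose values had also been seen. The 11 measured had a median of -0.59 under SPF housing (percentile 0.01). Under GF housing the median was -0.54 (percentile 6.02, inside the central 95% of random lists), and 1 gene, Tgtp2, was at least 2-fold lower in both pairs. Of 24 enteroendocrine cell genes, listed after Chga and Chgb were seen and without them, 17 were measured under GF housing. Their median was 0.84 (percentile 99.98), with 7 at least 2-fold higher on the KO-labelled array and 1 lower. Of the 7, only Neurod1 (1.31) and Sst (1.44) were above background on both GF arrays. Insm1, Scg2, Tph1, Gcg and Gfra3 counted as measured only through the KO-labelled array, where they were high. The general epithelial list also had a positive median on this pair (0.72, percentile 100). Under SPF housing 11 were measured with a median of 0.09 (percentile 79.5), and 0 of the 11 measured in both pairs were 2-fold higher in both.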
